A study of Rattus norvegicus with 2 samples.

How the data were processed

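Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on rat oligodendrocytes, the myelin-forming glia of the central nervous system. Per the labels' protocols, primary Sprague Dawley oligodendrocyte progenitors were differentiated for 3 days in the presence of T3, a thyroid hormone. Chromatin was cross-linked with formaldehyde, sonicated and precipitated with an antibody against Chd7 or against Sox10. There was 1 library per antibody.

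CASAVA, Bowtie2 and MACS and the genome build rn5 are named in the submitters' processing notes. Their versions and settings, the use of a control library and any filtering are not given in the sources used here. The authors deposited 1 peak list per antibody, with a chromosome, a start, an end and a caller score for each peak. Every deposited score was at least 50. The layout resembles a MACS score that grows with the significance of a peak, but neither list states the scale, so scores were used only to rank peaks within 1 list. The lists hold no read counts, and the sequencing depth behind each peak is therefore unknown. A stronger or deeper library gives more and wider calls, so differences in peak number, width or score between the antibodies cannot be read as differences in binding.

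The peaks were read as deposited, with no peak removed. Within each list no peaks overlapped each other. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. These counts were identical to those from bedtools 2.31.1. Coordinates are given 1-based on rn5.

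To show the overlap of unrelated positions, the Sox10 peaks of each chromosome were moved together around that chromosome's covered span by a random distance. This circular shift was drawn 1000 times and keeps the widths and spacing of the peaks. The one-sided permutation p is the number of shifts with at least the observed overlap plus 1, divided by the number of shifts plus 1. After rounding, 0.001 is the smallest value it can take. Assembly gaps were not removed from the span. The peaks outside the 20 autosomes and X were left in place. Shares carry 95% exact (Clopper-Pearson) binomial intervals, which cover counting error only. With 1 library per antibody there is no replicate error, and every p-value describes peaks within this pair of lists rather than a difference between conditions. The strongest and weakest quartiles of a list, and chromosome X and the autosomes, were compared with Fisher's exact test, two-sided, across peaks, which are not replicates. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

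The overlap procedure was tested on simulated data with the numbers and widths of the real 15255 Chd7 peaks on the autosomes and X. Peaks of both lists were placed independently and evenly along each chromosome, and Chd7 peaks that fell on an earlier one were dropped. The simulated lists thus lack the clustering of the real ones. They check the calculation and do not give the false-positive rate for clustered lists. With 0% planted overlap, 0 of 20 simulations gave p under 0.05. With 20% planted, the excess over shifted positions came out at 19.9% ± 0.085 (SD over simulations), and with 40% planted at 39.9% ± 0.091.

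The choices made before the data were examined were the overlap rule, the circular shift, the alternatives to both, and the rule for the peaks named in the text. That rule takes the 10 highest-scoring peaks of each list and the 10 overlapping pairs with the best mean rank of both scores, ties being ordered by width and then position. Alternatives included a 50% overlap, centres within 200 bp, peaks within 1 kb, the upper 50% of each list by score, lists of equal length, peaks over 3 kb left out, independent random placement and autosomes alone. Local shifts of 10 to 100 kb, and the removal of 1 Mb windows with 30 or more Chd7 peaks, were added after seeing the data. The same holds for the alternatives to the Sox10 strength comparison, to the comparison of X with the autosomes and to the counts of named peaks. The comparison of X with the autosomes was itself not among the planned results.

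An rn5 sequence and gene annotation were not used here. The planned analyses of peak position relative to genes, of genes and 15 fixed gene lists with a peak within 5 kb of a transcription start, and of sequence motifs in peaks were therefore not run, and no peak is assigned to a gene. Peaks are identified by position alone.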

Results

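The occupancy of Chd7 and Sox10 was mapped in rat oligodendrocytes after 3 days of differentiation. Chd7 is an ATP-dependent chromatin remodeler, and Sox10 is a transcription factor required for oligodendrocyte differentiation and myelin gene expression. The study asked where along the genome each protein sits in these cells and, by its title, concerns the interaction of both. The data are 1 peak list per antibody, without replicates.

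Sox10 peaks were more numerous and wider than Chd7 peaks. The Sox10 list held 38915 peaks and the Chd7 list 15310, a ratio of 2.54. Sox10 peaks had a median width of 654 bp (quartiles 522 and 838 bp) and Chd7 peaks of 315 bp (quartiles 249 and 426 bp). Together the Sox10 peaks covered 28.2 Mb and the Chd7 peaks 5.90 Mb. The median caller score was 116 for Sox10 and 67.2 for Chd7, both above the floor of 50 that each list shared. The score reached 3100 or more in 28 Sox10 peaks and 8 Chd7 peaks, and 26 Sox10 peaks sat at exactly 3100, so the strongest sites are not ranked further. All but 50 Sox10 and 55 Chd7 peaks lay on the autosomes or X. The Chd7 list had 2 peaks on the mitochondrial genome and the Sox10 list 0. Library depth is unknown, so these differences between lists carry no test.

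A large part of the Chd7 sites coincided with Sox10 sites. Of the 15310 Chd7 peaks, 6278 overlapped a Sox10 peak, a share of 41.0% (95% exact interval 40.2% to 41.8%). Shifted Sox10 positions overlapped 1.53% ± 0.10 (SD over 1000 shifts) of the Chd7 peaks and at most 1.85%, so the observed overlap was 26.9 times that of unrelated positions (one-sided permutation p = 0.001, the smallest the shifts can give). In the other direction, 6106 of the 38915 Sox10 peaks overlapped a Chd7 peak, a share of 15.7% (95% exact interval 15.3% to 16.1%) against 0.592% ± 0.040 after shifting (p = 0.001 in the same permutation test). Most Sox10 sites therefore had no Chd7 call. Both shares depend on list length: with the Sox10 list limited to its 15310 strongest peaks, 31.0% of Chd7 peaks and 30.2% of Sox10 peaks were shared. Shifts of only 10 to 100 kb, which keep the regional density of peaks, gave an expected Chd7 share of 2.47% ± 0.14, and the observed share was 16.6 times as large. Neither kind of shift is confined to open chromatin or to sequence where peaks can be called. Both ratios therefore include any tendency of the lists to fall in the same such places. No input list or list of another antibody was used here to measure that tendency.

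The shared sites were closely aligned. The lists formed 6283 overlapping pairs, in which the peak centres were a median of 69 bp apart (quartiles 31 and 132 bp). In 92.9% of the pairs the whole Chd7 peak lay within the Sox10 peak. A Sox10 centre lay within 200 bp of 35.2% of the Chd7 centres on the autosomes and X, against 0.542% ± 0.056 (SD over 100 shifts) for shifted positions. Within 10 kb the shares were 53.4% observed and 21.1% ± 0.44 expected, and within 100 kb they were 84.9% and 74.3% ± 0.93. Both wider shares include the Chd7 peaks that overlap Sox10, so they do not show nearness beyond the overlap itself. The Chd7 peaks that overlapped no Sox10 peak lay a median of 37.0 kb from the nearest Sox10 centre. No shifted value was computed for this median.

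Stronger sites were shared more often in both lists. Among Sox10 peaks the shared portion rose with each decile of caller score, from 3.39% in the weakest to 47.0% in the strongest decile. The strongest quartile of Sox10 peaks overlapped Chd7 in 37.3% of cases and the weakest in 3.70%, a difference of 33.6 percentage points ± 0.53 (SE across peaks). Among Chd7 peaks, 55.4% of the strongest quartile and 27.0% of the weakest overlapped Sox10, a difference of 28.4 points ± 1.08 (SE across peaks, Fisher's exact test p = 1.6e-142). The Chd7 trend was not monotonic: the share rose from 24.5% in the weakest decile to 61.1% in the ninth and was 50.0% in the strongest. Within that decile the share depended on how many peaks were taken. Of the 50 strongest Chd7 peaks 35 overlapped Sox10 (95% exact interval of the share 55.4% to 82.1%), of the 100 strongest 56.0% (45.7% to 65.9%), of the 200 strongest 42.0% (35.1% to 49.2%), of the 500 strongest 34.2% (30.05% to 38.5%) and of the 1000 strongest 43.1% (40.005% to 46.2%). Many of the strongest Chd7 peaks lay in 1 Mb windows with 30 or more Chd7 peaks: 29 of the 50 strongest and 51 of the 100 strongest. Outside these windows 9 of 21, 16 of 49, 28 of 112, 79 of 297 and 319 of 692 overlapped Sox10 in the same order, shares of 42.9% for the first and 26.6% for the 500 strongest. Inside them the counts were 26 of 29, 40 of 51, 56 of 88, 92 of 203 and 112 of 308, shares of 89.7% for the first and 45.3% for the 500 strongest. For the 50 to 1000 strongest Sox10 peaks, inside and outside together, the shares overlapping Chd7 lay between 56.2% and 68.0%.

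**Figure D1:**
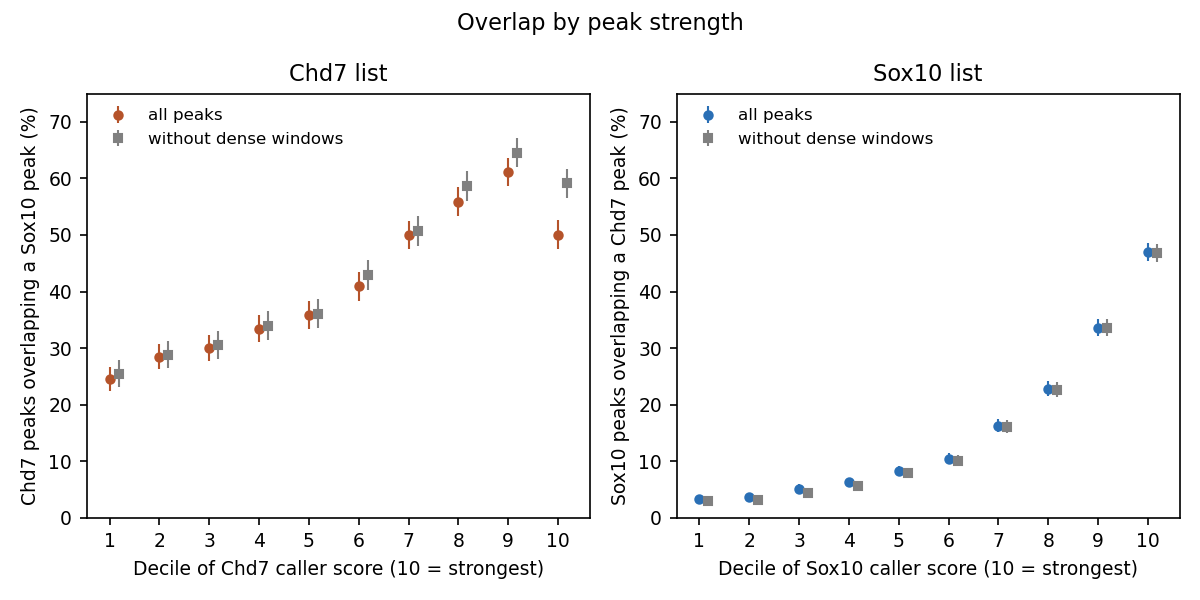
Share of Chd7 peaks overlapping a Sox10 peak (left) and of Sox10 peaks overlapping a Chd7 peak (right), in percent, by decile of the caller score of the ranked list. Coloured circles are all peaks, grey squares leave out 1 Mb windows with 30 or more Chd7 peaks, and bars are 95% exact intervals; the Sox10 share climbs to 47.0% in the strongest decile, while the Chd7 share peaks at 61.1% in the ninth.

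Averaged over classes of peak width, the strength trend was smaller than over all peaks. Caller score and width were correlated across peaks (Spearman's rho 0.54 for Chd7 and 0.69 for Sox10; peaks are not independent replicates). Shared Chd7 peaks had a median width of 375 bp and unshared ones of 278 bp, and for Sox10 these widths were 839 and 623 bp. Within quartiles of width, the mean difference between strongest and weakest peaks was 20.4 points for Sox10 and 6.57 points for Chd7. Score quartiles were redrawn within each width class, so these values do not compare the same score ranges as the differences over all peaks. For the narrowest quartile of Chd7 peaks the difference was -1.17 points, and for the widest it was 12.6 points. For Sox10 it was 5.35 points in the narrowest quartile and 38.4 in the widest, the latter above the 33.6 points over all Sox10 peaks. Over the 6283 pairs, the Chd7 and Sox10 scores had a Spearman's rho of 0.36 across pairs.

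The pairs with the best mean rank in both lists have high caller scores for both proteins by the way they were chosen. The first lay on chromosome 2, where a Chd7 peak at 216836026 to 216837728 (score 682) overlapped a Sox10 peak at 216834247 to 216837989 (score 3100). A second pair stood close by on the same chromosome, with Chd7 at 216822213 to 216824035 (score 410) and Sox10 at 216822135 to 216825300 (score 3100). Another on chromosome 2 joined Chd7 at 68242204 to 68242761 (score 413) with Sox10 at 68241878 to 68243005 (score 3100). On chromosome 17, a Chd7 peak at 42278623 to 42279502 had a score of 405, within a Sox10 peak of score 2923. Chromosome 4 held Chd7 peaks at 8477556 to 8478448 (score 390.02) and at 49657287 to 49658311 (score 336), and chromosome 18 at 55799578 to 55800455 (score 387) and 49983770 to 49984656 (score 362). The remaining pairs of this group were on chromosome 3, with Chd7 at 121980784 to 121981675 (score 481), and on chromosome 1, with Chd7 at 250663749 to 250664834 (score 316). The Sox10 peaks of the 10 pairs had scores from 1850 to 3100.

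Of the 10 highest-scoring Sox10 peaks, 8 overlapped a Chd7 peak, with Chd7 scores from 86.8 to 682. The highest were on chromosome 7, at 37622288 to 37623782 (score 3104.2, with a Chd7 peak of score 189) and at 141869412 to 141870873 (score 3103.79, with a Chd7 peak of score 86.8). The exceptions were both on chromosome 1, at 154720417 to 154723410 and 225874351 to 225876329, where the score was 3100 and no Chd7 peak overlapped. Only 1 of the 10 had a Chd7 centre within 200 bp of its own centre. Those at exactly 3100 were the widest of the 26 peaks with that score, so this count describes wide Sox10 peaks rather than strong ones in general. The Sox10 peak at 26151771 to 26157459 on chromosome 15 was 5689 bp wide, and its Chd7 peak (score 116) covered 26151834 to 26153764.

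Of the 10 highest-scoring Chd7 peaks, 8 overlapped a Sox10 peak, and 6 came from a single stretch of chromosome 1 between 187 and 189 Mb. That stretch held 184 Chd7 peaks with a median score of 253, of which 52 overlapped Sox10. It also held 50 Sox10 peaks with a median score of 183, of which 44 overlapped Chd7. The Chd7 peaks at 187677275 to 187678369, 187599088 to 187599871, 188256120 to 188256879 and 187858228 to 187858863 all scored 3100, over Sox10 peaks that scored 630, 149.67, 366 and 919. The Chd7 peak at 187766771 to 187769180, also at 3100, overlapped no Sox10 peak. Outside this stretch, a Chd7 peak on chromosome 13 at 38638377 to 38641444 (score 3100) overlapped a Sox10 peak of score 1170. The peak on chromosome 19 at 67047774 to 67048984 (score 3100) overlapped no Sox10 peak. The others were at 43095 to 43688 on chromosome 3 (score 3100) and at 1488337 to 1490761 on chromosome 12 (score 3021).

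**Figure D2:**
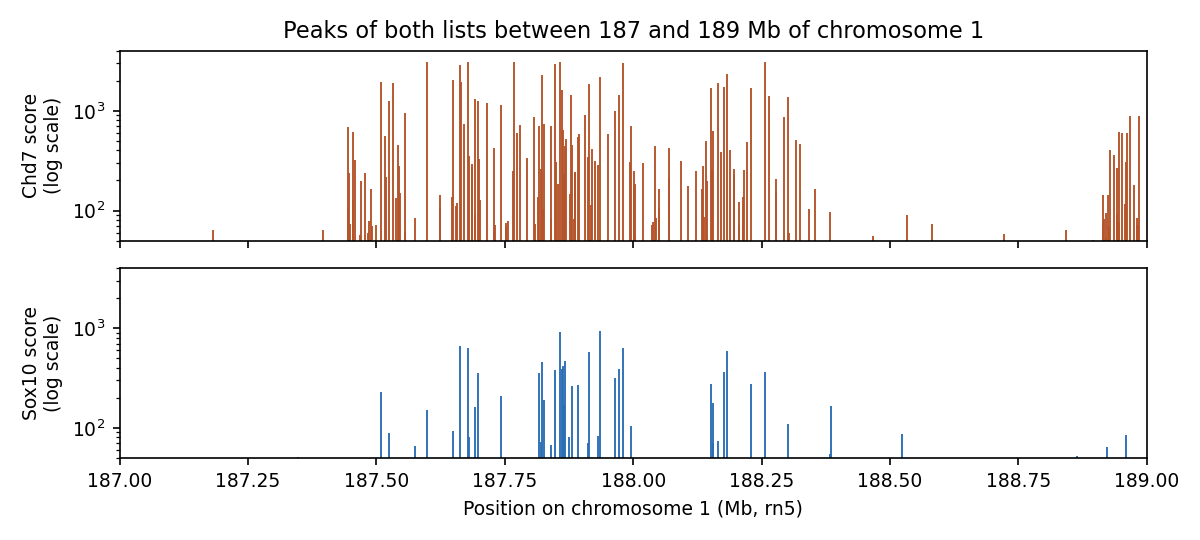
Chd7 peaks (top) and Sox10 peaks (bottom) between 187 and 189 Mb of chromosome 1 on rn5; the horizontal axis is the position in Mb, and each line marks a peak's centre and rises to its caller score on a log axis that starts at 50. The stretch holds 184 Chd7 and 50 Sox10 peaks, and the Chd7 scores reach 3100.

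Dense stretches of this kind were few. Of the 1 Mb windows with a peak of either list, 26 held 30 or more Chd7 peaks, with a median of 52.5 Chd7 peaks against 4 in the other 2752. They contained 1410 Chd7 peaks, or 9.21% of the list, and 20.5% of these overlapped Sox10 (95% exact interval 18.4% to 22.7%), against 43.1% outside. The windows were also richer in Sox10 peaks, with a median of 22 against 13 elsewhere, a ratio of 1.69 (one-sided permutation p = 1e-05 on the mean, the smallest that 100000 draws can give). They held 604 Sox10 peaks for the 1410 Chd7 peaks, which limits the Chd7 share. Of these Sox10 peaks 235 overlapped Chd7 (38.9%, 95% exact interval 35.0% to 42.9%), against 15.3% outside. The windows were chosen for their many Chd7 peaks, which by itself raises the Sox10 share. No shifted overlap was computed within them. Without these windows, the shared portion was 43.1% of Chd7 and 15.3% of Sox10 peaks, and the difference between Chd7 quartiles was 33.3 points. The strongest Chd7 decile was then shared in 59.1% of cases and the ninth in 64.5%. None of the 10 best-ranked pairs and none of the 10 highest Sox10 peaks lay in such a window, while 7 of the 10 highest Chd7 peaks did.

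The overlap held on every chromosome but was lowest on X. Among the 20 autosomes, the share of Chd7 peaks that overlapped Sox10 ran from 31.8% on chromosome 19 to 55.8% on chromosome 10. On X it was 11.3%, or 71 of 631 peaks (95% exact interval 8.89% to 14.0%), against 42.4% over the autosomes. The share on X was thus lower by 31.2 percentage points (-31.2, X minus autosomes, Fisher's exact test p = 8.2e-64). This comparison was not among the planned results, and its p-value takes no account of X being the chromosome with the lowest share. Sox10 peaks were sparse on X, with 5.42 per Mb of covered span against 13.9 on the autosomes, while Chd7 had 4.09 against 5.33 per Mb. X therefore held 4.14% of the placed Chd7 peaks and 2.15% of the placed Sox10 peaks. Of the Sox10 peaks on X, 8.00% overlapped Chd7 (95% exact interval 6.26% to 10.1%), against 15.9% on the autosomes (Fisher's exact test p = 2.6e-11). Shifted positions on X gave an expected Chd7 share of 0.520%, so the observed overlap there was still 21.6 times that of unrelated positions.

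**Figure D3:**
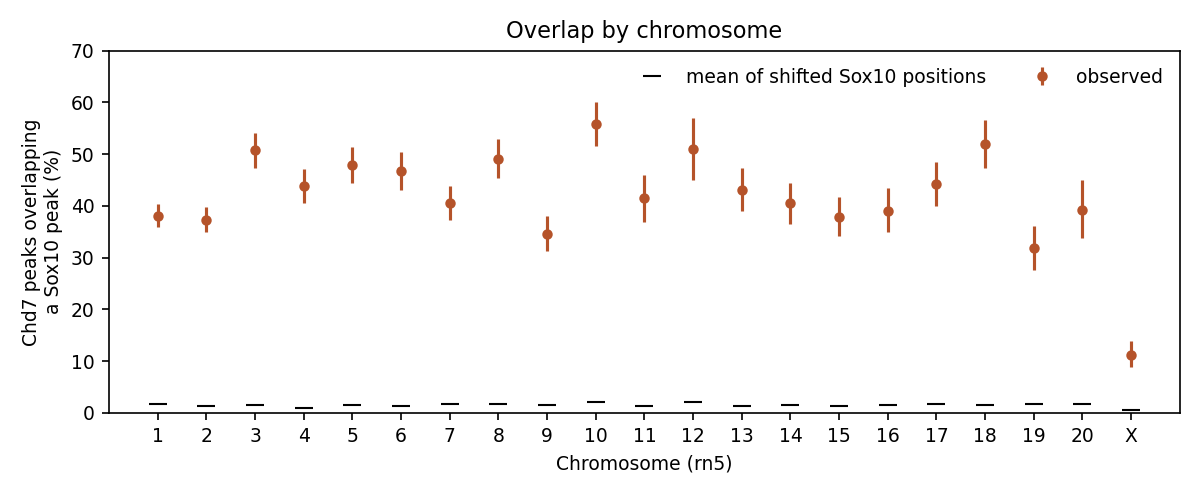
Share of Chd7 peaks that overlap a Sox10 peak, in percent, on each chromosome of rn5; circles are the observed shares with 95% exact intervals, and black dashes are the mean of 1000 shifts of the Sox10 peaks. X stands at 11.3%, below the 31.8% of chromosome 19, and every observed share lies above its shifted mean.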

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

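All 20 alternative values for the shares of overlapping peaks stayed above their shifted or random positions (permutation p = 0.001 in each). The Chd7 share ran from 31.0% with lists of equal length to 45.0% in the upper 50% of each list by score, and the Sox10 share from 13.8% with centres within 200 bp to 30.2% with lists of equal length. The excess of the Chd7 share over unrelated positions, 26.9 times in the report, was 10.6 times when peaks within 1 kb counted as shared, 16.6 times with local shifts, 43.2 times with lists of equal length, 46.4 times in the upper 50% of each list and 61.6 times with centres within 200 bp. The Chd7 strength difference of 28.4 points was 25.5 points between deciles and a mean of 6.57 points within quartiles of width, where score quartiles were redrawn. The Sox10 difference of 33.6 points was 43.6 and 20.4 points under those settings. The lower share on X, a comparison outside the plan, ranged from -34.0 to -27.3 points over 6 alternatives, all added after seeing the data. The count of the 10 highest Sox10 peaks with a Chd7 peak went from 8 to 1 with centres within 200 bp. Leaving out replicates was not possible with 1 library per antibody. No paired analysis was possible because each antibody has 1 library. The comparisons of gene positions, gene lists and motifs, with their other settings, were not run, since no rn5 annotation or sequence was used here. The depth of the libraries is unknown, so sites of either protein below the score floor of 50 cannot be seen.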

Other observations

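Most shared sites stood apart from each other. Of the 6274 shared Chd7 peaks on the autosomes and X, 5307 stood alone when peaks up to 10 kb apart were joined, and 72 groups held 3 or more, 42 of them outside the 1 Mb windows dense in Chd7 peaks. Groups of 5 shared peaks outside those windows lay on chromosome 14 at 46845725 to 46863563, chromosome 19 at 5808024 to 5827232 and chromosome X at 351194 to 367146. The longest group had 9 peaks over 41.5 kb on chromosome 7, from 22530465 to 22571923, inside a dense window. Chd7 peaks with another Chd7 peak within 10 kb were shared less often, at 31.2%, than those without one, at 44.7%. The hypothesis that the shared state of neighbouring Chd7 peaks is nonetheless alike was tested on the 2591 pairs of neighbouring Chd7 peaks within 10 kb: in 523 both were shared, against 420 ± 20 (SD) in 1000 random relabellings within chromosomes (one-sided permutation p = 0.001), a ratio of 1.24. The relabellings within chromosomes do not keep the lower share of peaks that have a neighbour. The ratio therefore mixes how often neighbours were shared with how alike their states were, and does not measure the likeness alone. In 177 pairs a single Sox10 peak spanned both Chd7 peaks, which could by itself give an excess of pairs with both shared. Among 1006 neighbours 2 to 10 kb apart outside dense windows, 253 pairs were both shared against 188 ± 12 expected (p = 0.001 in the same permutation test). An excess was thus also present at distances beyond the width of most Sox10 peaks. How many of the 253 pairs lay under a single Sox10 peak is not given here, and 103 Sox10 peaks were wider than 3 kb. The relation of these neighbours to genes or to open chromatin was not tested.

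Both tests on dense windows were chosen after the result they bear on was seen. So were the test of dense windows among the strongest Chd7 peaks and the test above on neighbours 2 to 10 kb apart. The same holds for 3 tests on X: the reweighting by Chd7 score and width, the count of dense windows, and the share of Sox10 peaks overlapping Chd7. The excess over shifted positions on X is not counted among these 3. The test of narrow peaks below was written down first, as was the test of all neighbours within 10 kb. The study's groups are the antibodies alone, so no biological explanation was tested for the patterns below.

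The 26 windows dense in Chd7 peaks may reflect a regional excess of reads, such as a copy number difference from the reference or collapsed repeats. All Sox10 peaks were more frequent there, with a median of 22 per window against 13, which goes with such an excess but also counts the peaks that overlap the many Chd7 peaks. Sox10 peaks that overlap no Chd7 peak had a median of 11 per window both there and elsewhere, a ratio of 1, with means of 14.2 and 11.8 (one-sided permutation p = 0.07), and leaving out overlapping peaks removes most where Chd7 peaks are dense, so it stays open. Whether these are ordinary Chd7 sites beside Sox10 sites is open too. Of the Chd7 peaks there 20.5% overlapped Sox10 against 43.1% outside, but the number of Sox10 peaks limits that share. Of the Sox10 peaks there 38.9% overlapped Chd7 against 15.3% outside. The windows were chosen for their many Chd7 peaks, which raises the latter share, so neither share decides it. Of the 50 strongest Chd7 peaks of the list, 29 lay in the dense windows and 26 of these overlapped Sox10, and neither explanation was tested on them. No input library, sequence or annotation was used here that could separate these explanations.

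The 500 strongest Chd7 peaks overlapped Sox10 less often than those of the ninth decile, at 34.2% against 61.1%. Dense windows are not the cause among these 500, since 92 of the 203 peaks inside them overlapped Sox10 (45.3%) and 79 of the 297 outside (26.6%, 95% exact interval 21.7% to 32.0%). Among the 1000 strongest the direction turned, with 36.4% inside and 46.1% outside, and leaving the windows out narrowed the step from the ninth to the strongest decile from 61.1% and 50.0% to 64.5% and 59.1%, so they contribute to that step. Peaks narrower than 460 bp, the median width of the ninth decile, are not the whole cause either. Of the 335 peaks at least 460 bp wide, 41.8% overlapped (36.5% to 47.3%), though the 165 narrower ones stood at 18.8% (13.1% to 25.6%). The cut does not grow with the score, so peaks that are narrow for their height can pass it. Narrow, tall read stacks are therefore not excluded. Signal from repeats and Chd7 sites without Sox10 both remain possible.

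Weaker or narrower Chd7 peaks are not the whole cause of the low overlap on X. Autosome peaks reweighted to the 16 score and width classes of X gave 35.4%. That is below the unweighted 42.4% but well above the upper bound of 14.0% on X. Dense Chd7 windows cannot account for it, as 0 of the 26 lay on X. Whether sparse Sox10 calls on X account for it is open. The excess over shifted positions, 21.6 times, lay within the autosome range of 19.3 to 42.6 times, as such calls would give. The share of Sox10 peaks that overlap Chd7 was 8.00% on X (95% exact interval 6.26% to 10.1%) and at least 13.0% on every autosome. Fewer Sox10 calls alone would not lower that share, but the calls on X were also weaker. Their median score was 99.4, against 107 to 138 on the autosomes, and weaker Sox10 peaks were shared less often. Across autosomes, though, a lower median score did not go with a lower share. Chromosomes 15, 2 and 13 had the lowest medians (106.88, 107.28 and 107.69) and shares of 16.5%, 16.3% and 18.1%. Chromosomes 12, 19, 10 and 20 had the highest medians, from 128 to 138, and shares from 13.0% to 15.0%. These values argue against the lower median score alone as the cause on X. No reweighting of Sox10 peaks by score was made. What lowers both shares is open, and the number of X copies in these cells was not known.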
